A study of Triticum dicoccoides with 12 samples.

How the data were processed

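Transcript levels were measured in 12 samples of wild emmer wheat, 3 for each combination of a drought-resistant (R, Y12-3) or drought-susceptible (S, A24-39) genotype with a well-watered or terminal drought regime. The samples were leaf-like organs (phyllome) of plants at 10 weeks of age in reproductive growth, per the labels. Total RNA was biotin-labelled with the Affymetrix one-cycle protocol, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The last line of the longer description names the same genotype and regime for all samples and was not used. Nothing in the labels says whether the 3 samples of a group came from separate plants, so p-values measure the spread between these samples, which may be partly technical.

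The deposited values are signal intensities on a linear scale, made with MAS5, per the submitters' processing notes. The version, the masking of probes and the scaling target are not given in the sources used here. The table holds 61290 probe sets, with no missing value and no pair of arrays with identical values. The mean without the highest and lowest 2% of probe sets was 500.3 on each array, so the deposited intensities had been scaled to 1 trimmed mean per array. No floor was seen, and the lowest intensity was 0.15499. No present or absent call was used here. The level of noise was therefore taken from 23 probe sets of the array that target no wheat transcript (276 values). Their median was 18.7, their 95th percentile 129 and their highest value 350. A signal under 129 is called below the control level. Where every array of a group lay below it, the ratio to the brighter group is given as "at least N-fold", from the means of log2 values with each dim array set to the higher of its own signal and 129.

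From these intensities, log2(value + 16) was computed, with no further scaling between arrays. Changes on this scale understate those of dim probe sets. The 111 control probe sets (AFFX) were left out of the tests. The 64 reporter probe sets (RPTR) were left out as well, which departs from the filter fixed beforehand and was decided after the data were seen. Of the other 61115 probe sets, 38398 (62.8%) lay above their array's median on at least 3 of the 12 arrays and were tested. Means of the 4 groups were fitted to all 12 arrays with limma 3.58.1 (lmFit, eBayes with a trend) in R 4.3.3. The 6 contrasts named next were tested, and a probe set past a Benjamini-Hochberg adjusted p of 0.05 within a contrast is called higher or lower. The contrasts were drought within R, drought within S, their mean, R minus S in each regime, and the difference between the drought effects (the interaction). Values are given as log2 change ± SE. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

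Gene names came from the platform annotation, dated 2007. It pairs 1273 probe sets with 1 gene each (771 genes) and none with several, and it leaves 59842 unnamed. Only 13 of these genes (19 probe sets) have a symbol that is not a bare locus number, and 8 of the 13 (11 probe sets) were tested. No gene ID and no accession was shared with the table of wild emmer genes of assembly WEW_v2.1, so no symbol was updated and no coordinates are given. The rule fixed beforehand named, per contrast, the 10 highest and 10 lowest called genes with a symbol whose arrays separated the groups, the members of gene lists, and the control probe sets for RNA quality. Because 8 genes could be tested, values are given for them whether called or not. At most 2 probe sets that were higher and 2 that were lower per contrast, with or without a locus number, were added after their values were seen. They are given by the locus number, or as unnamed probe sets where the annotation lists no gene. Of 31 gene lists fixed beforehand, 7 matched a gene and 5 had a tested gene, 1 each, so that no list reached the 3 genes needed for a set test. Different probe sets of a gene were tested separately.

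The fit was tested on simulated data for 38398 probe sets with the measured spread, of which 200 differed in the R drought group. The drought contrast within R recovered 4.48% of the 2-fold, 32.8% of the 4-fold and 71.2% of the 8-fold changes, with 3 unchanged probe sets called. The interaction recovered 1.49%, 17.9% and 34.8%, with 0 unchanged probe sets called. With 10% of probe sets changed 4-fold, the recovered shares were 68.3% and 42.2%. The number of arrays limits the precision, and the median SE of a log2 change between 2 groups was 0.473.

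Alternatives fixed before the data were examined were pseudocounts of 1 and 64, median scaling over the tested probe sets, quantile normalization, no filter, a filter on the mean, eBayes without a trend, array weights, a fit to the groups compared, the replicate number as a block, each array left out, and an added 2-fold threshold. Scaling to the hybridization control probe sets or to the poly-A control probe sets, keeping the reporter probe sets, and setting signals under the control level to it (for probe sets above it on at least 3 arrays) were added after the data had been seen. Only the replicate numbers connect samples of different groups, and no scan date or other batch was used here.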

Results

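Leaf-like organs of a drought-resistant (R) and a drought-susceptible (S) genotype of wild emmer wheat, a tetraploid wild relative of cultivated wheat, were profiled on a wheat oligonucleotide array after good watering or terminal drought. Each of the 4 groups held 3 arrays. The comparisons address how transcript levels respond to terminal drought in each genotype, how the genotypes differ in each water regime, and whether their drought responses differ. The median signal of an array lay between 58.6 and 151.5. It was 111 ± 37.3 in well-watered R, 66.6 ± 11.3 in R under drought, 77.2 ± 4.14 in well-watered S and 77.05 ± 0.833 in S under drought (SD, n = 3). Well-watered R replicate 3 stood apart, with 33042 probe sets above the control level against 21848 to 27343 on the other 11 arrays. Within groups, arrays correlated with Pearson's r of 0.876 to 0.939 across probe sets, which are not independent replicates. Water regime accounted for 42.6% of the sum of squares of the log2 values, genotype for 18.8%, their interaction for 6.84% and the spread within groups for 31.8%. The spread within groups also adds to the share of each of the other terms. A large part of the 6.84% would therefore arise with no interaction.

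Terminal drought lowered FBP, GAPN and petC and raised sucrose synthase in both genotypes. FBP, fructose-1,6-bisphosphatase of the Calvin cycle and sucrose synthesis, fell by 3.20 ± 0.45 on the log2 scale in R (adjusted p = 1e-04, limma) and by 3.32 ± 0.45 in S (adjusted p = 0.00011). Its signal was 12717 ± 2296 in well-watered R and 1700 ± 1134 under drought, and 15729 ± 285 and 1586 ± 361 in S (SD, n = 3). GAPN, the non-phosphorylating NADP-dependent glyceraldehyde-3-phosphate dehydrogenase, fell by 3.54 ± 0.49 in R (adjusted p = 8.9e-05) and by 2.86 ± 0.49 in S (adjusted p = 0.00065). petC, the Rieske iron-sulfur protein of the photosynthetic cytochrome b6f complex, changed by −1.62 ± 0.29 in R (adjusted p = 0.00057) and by −1.16 ± 0.29 in S (adjusted p = 0.0079). Sucrose synthase, which cleaves or forms sucrose, is covered by 3 control probe sets along its transcript. They rose by 2.48 ± 0.29, 2.52 ± 0.35 and 3.10 ± 0.42 in R (3′, middle and 5′) and by 2.15, 2.34 and 2.31 in S, with adjusted p between 2.1e-05 and 0.001. FBP, GAPN and sucrose synthase kept their direction and their call in each genotype under all 4 other scalings. petC kept its direction. It lost its call with a smaller change in R under hybridization control scaling (−0.69, adjusted p = 0.28) and in S under quantile normalization (−0.83, adjusted p = 0.077) and poly-A control scaling (−0.76, adjusted p = 0.27), and with nearly the same change in S under hybridization control scaling (−1.11, adjusted p = 0.095).

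**Figure D1:**
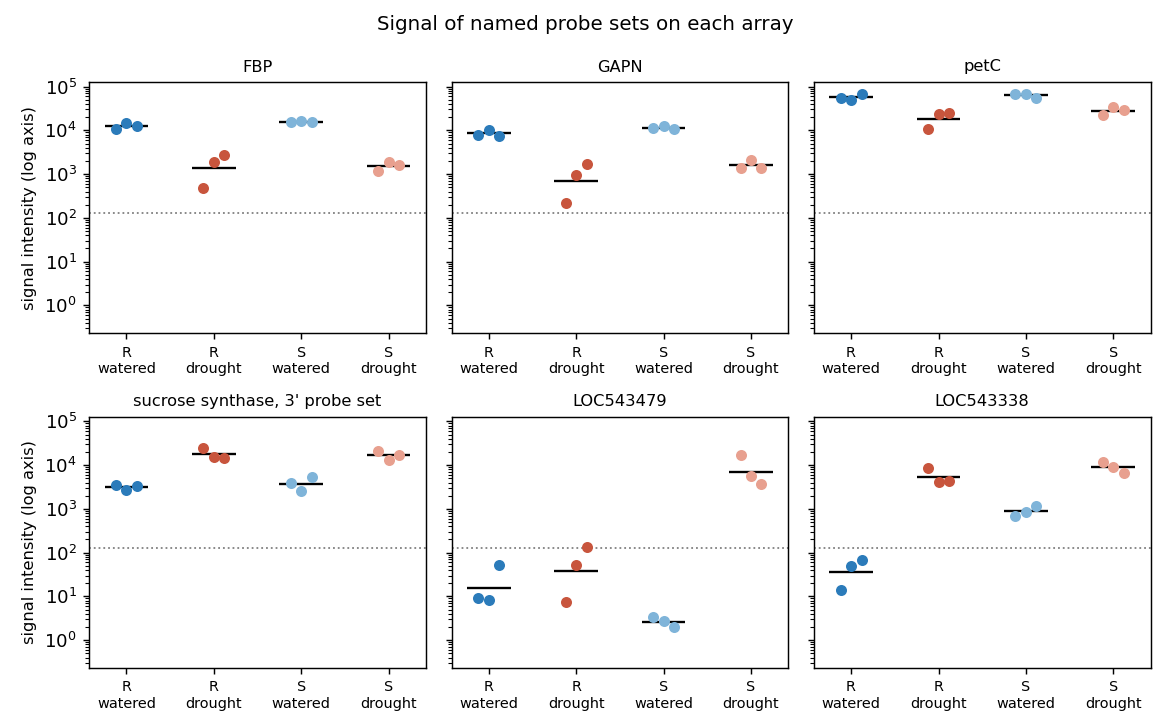
Signal intensity (log axis) of 6 named probe sets on each of the 12 arrays, by genotype and water regime. Points are arrays, bars are geometric means of 3 arrays, and the dotted line is the control level of 129. FBP, GAPN and petC lie lower under drought in both genotypes and sucrose synthase higher, while LOC543479 is far above the control level in S under drought alone and LOC543338 is below it in well-watered R alone.

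Smaller differences were measured for the other genes with a symbol. SAHH, S-adenosylhomocysteine hydrolase of the methyl cycle, changed by −0.93 ± 0.25 in R (adjusted p = 0.0099) and by −1.07 ± 0.25 in S (adjusted p = 0.0055). Its second probe set measured −0.90 ± 0.31 and −1 ± 0.31 (adjusted p = 0.038 and 0.027). Relative to the median change of all tested probe sets, which was −0.322 in R, the change of the first in R was −0.61, and it was 0 under hybridization control scaling. CAT1, a catalase that breaks down hydrogen peroxide, changed by −0.61 ± 0.22 in R (adjusted p = 0.043) and −0.90 in S (adjusted p = 0.0067), and TUBA, an alpha-tubulin, by −0.71 ± 0.24 (adjusted p = 0.035) and −0.75 (adjusted p = 0.032). In R, both genes turned to 0.32 and 0.22 under hybridization control scaling, and relative to the median change they stood at −0.29 and −0.39. The calls of SAHH (first probe set), CAT1 and TUBA in R were also lost with median scaling, with smaller changes of −0.43, −0.11 and −0.21 (adjusted p = 0.27, 0.82 and 0.63), and with poly-A control scaling, with −0.81, −0.49 and −0.59 (adjusted p = 0.2, 0.46 and 0.38), and that of CAT1 with quantile normalization (−0.55, adjusted p = 0.14). In S, the calls of these 3 were lost with hybridization control scaling while the changes stayed at −1.02, −0.86 and −0.71 (adjusted p = 0.11, 0.23 and 0.35). They were lost with smaller changes of −0.67, −0.51 and −0.36 with poly-A control scaling (adjusted p = 0.31, 0.45 and 0.63). CAT1 in S also lost its call with quantile normalization (−0.56, adjusted p = 0.15), and TUBA in S with median scaling and quantile normalization at little changed values of −0.70 and −0.69 (adjusted p = 0.078 and 0.057). The second SAHH probe set lost its call in R with median scaling (−0.39), hybridization control scaling (0.03) and poly-A control scaling (−0.77), and in S with quantile normalization (−0.87), hybridization control scaling (−0.96) and poly-A control scaling (−0.60), with adjusted p of 0.061 to 0.97. TBP1, a TATA-binding protein of the transcription machinery, rose by 0.77 ± 0.24 in R (adjusted p = 0.025) and measured 0.16 in S (adjusted p = 0.69), with an interaction of 0.61 that did not pass the threshold (adjusted p = 0.47). With poly-A control scaling its rise in R was 0.89, no smaller, and did not pass the threshold (adjusted p = 0.15). XTH, a xyloglucan endotransglucosylase/hydrolase of the cell wall, lay above the control level on 3 of the 12 arrays, all of S, and passed the threshold in neither genotype (adjusted p = 0.83 and 0.24), so its drought response was not measured here. Dimmer second probe sets of CAT1 and FBP measured −1.43 and −2.08 in R (adjusted p = 0.045 and 0.018) and −0.25 and −0.01 in S (adjusted p = 0.78 and 1), with interactions that did not pass the threshold (adjusted p = 0.51 and 0.33). The second FBP probe set lay above the control level on 2 of the 12 arrays, both of well-watered R, so its value in S is not a measured change and its size in R is not exact. The call of the second CAT1 probe set in R was lost under all 4 other scalings, at −0.57 to −1.31 (adjusted p = 0.12 to 0.5), and that of the second FBP probe set under hybridization control scaling, at −1.31 (adjusted p = 0.11). The dehydrin-type gene COR410, the thionin genes THI1.1, THI1.2 and TTHV, PFK, and second probe sets of TUBA and petC were below the filter, and no more than 1 of the 12 arrays of each lay above the control level.

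Some calls lay so near the threshold that leaving out 1 array lost them, though each change kept its direction. An array of S left out does not alter the change in R, only its error and adjusted p. CAT1 in R lost its call without any 1 of 8 arrays (R well-watered replicates 1 and 2, R drought replicates 1 and 3, the 3 S well-watered arrays and S drought replicate 1), with changes of −0.73 to −0.44 and adjusted p up to 0.16. The second SAHH probe set lost it in R without any 1 of 7 arrays (R well-watered replicates 1 and 3, the 3 R drought arrays, S well-watered replicate 1 and S drought replicate 3), with −1.24 to −0.50 and adjusted p up to 0.17, and in S without S well-watered replicate 1 or 3 or S drought replicate 1 or 3 (−1.17 to −0.82, up to 0.12). TUBA lost it in R without R well-watered replicate 1 or 2 or R drought replicate 1 (−0.86 to −0.50, up to 0.14), and in S without S well-watered replicate 2 or 3 or S drought replicate 1 or 3 (−0.94 to −0.61, up to 0.13). TBP1 lost it in R without R well-watered replicate 3 or R drought replicate 1 or 2 (0.53 to 0.91, up to 0.11). The second probe set of CAT1 lost it in R without any 1 of the 6 R arrays, S well-watered replicate 3 or S drought replicate 1 (−1.63 to −1.22, up to 0.14), and that of FBP without R well-watered replicate 3 or R drought replicate 1 (−2.65 to −1.53, up to 0.087). The ranges of change, here and for the control transcripts, are over the 12 arrays left out in turn.

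Of 38398 probe sets tested, drought changed 12824 in R, 5216 higher and 7608 lower. The probe sets with the highest log2 change, chosen after their values were seen and paired with no gene, were at least 365-fold and 372-fold higher (adjusted p = 2e-10 and 4.6e-10, limma), with 47608 ± 8409 and 48280 ± 5526 signal under drought (SD, n = 3). The lowest 2, also unnamed, were at least 333-fold and 341-fold lower (adjusted p = 3.5e-06 and 2.9e-08). Of locus-numbered genes, LOC542888 was at least 94-fold higher (adjusted p = 1.3e-06), LOC100125738 went from 115 ± 111 to 18048 ± 13181 signal (SD, n = 3), and LOC543355 and LOC543256 changed by −6.73 ± 0.73 and −6.04 ± 0.66 on the log2 scale (adjusted p = 3.8e-06, 1.4e-05 and 1.5e-05). At least 2-fold changes were found in 11072 of the called probe sets. The median change of −0.322 makes the direction of small changes depend on the scaling. The split was 7764 higher and 4464 lower with median scaling, 6219 and 5809 with quantile normalization, 8596 and 2093 with hybridization control scaling, and 3816 and 4704 with poly-A control scaling. Without well-watered R replicate 3, 10817 probe sets were called, 4700 higher and 6117 lower.

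In S, drought changed 10461 probe sets, 5165 higher and 5296 lower, with a median change of −0.025 over all tested. With poly-A control scaling the split was 4997 higher and 2249 lower. Hybridization control scaling called fewer, 6584, with 3460 higher and 3124 lower. The highest 2 unnamed probe sets were at least 423-fold and 307-fold higher (adjusted p = 3.2e-10 and 1.5e-07), while of the lowest 2 one was at least 473-fold lower (adjusted p = 2.6e-05) and the other went from 95892 ± 12246 to 111 ± 179 (SD, n = 3). LOC542888 was at least 89.7-fold and LOC543479 at least 54.6-fold higher (adjusted p = 1e-06 and 1.4e-06). LOC542989 was at least 41.5-fold lower, and LOC543355 fell by 5.89 ± 0.71 on the log2 scale (adjusted p = 5.5e-06 and 3.8e-05). The LOC543355 value in S comes from a different probe set than the one given for R, so these values do not compare the genotypes. At least 2-fold changes were found in 8973 probe sets. Without well-watered R replicate 3, 10651 probe sets were called.

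**Figure D2:**
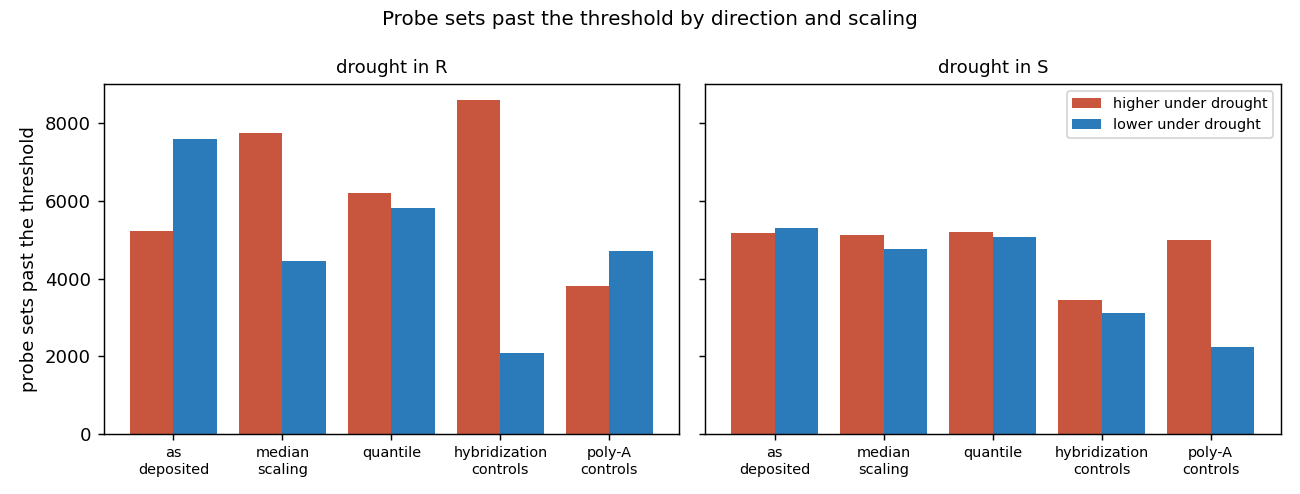
Number of probe sets past the threshold that were higher or lower under drought in R (left) and S (right), with the values as deposited and with 4 other scalings. In R the larger share is lower as deposited (7608 of 12824) and higher with median scaling (7764 of 12228), while in S it is 5165 higher and 5296 lower as deposited and 4997 and 2249 with poly-A control scaling.

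Averaged over the genotypes, drought changed 15887 probe sets, 6803 higher and 9084 lower, and the split was 8926 and 6667 with median scaling, 9006 and 4406 with hybridization control scaling, and 6731 and 5476 with poly-A control scaling. FBP, GAPN and petC changed by −3.26, −3.20 and −1.39 on the log2 scale (adjusted p = 1.9e-06, 4.8e-06 and 6.7e-05). Without well-watered R replicate 3, the count was 15094. Where a gene had 2 or more called probe sets, these had the same direction for 64 of 69 genes on average, 59 of 61 in R and 48 of 50 in S, but for 4 of 6 in each comparison of the genotypes.

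Probe sets called for drought in both genotypes nearly always had the same direction. A total of 3461 probe sets were higher in both and 4013 lower in both, where independent lists would share 702 and 1049, and 37 were called in opposite directions against 1743. Both lists come from the same fit, which shares the error of each probe set, so the numbers for independent lists can be too low. That sharing would raise the opposite count as well. The log2 changes of R and S, which share no array, correlated with r = 0.74 and rho = 0.652 across 38398 probe sets, which are not independent replicates. A further 5313 probe sets were called in R and not in S and 2950 in S and not in R. Of these 8263, 38 passed the test of the interaction, so a different response was not shown for the others. As a summary per array, the drought response score was the mean log2 of the probe sets higher under drought on average minus that of the lower ones. It rose from −0.80 ± 0.14 to 2.60 ± 0.48 in R and from −1.03 ± 0.14 to 2.05 ± 0.56 in S (SD, n = 3). The rises of 3.4 and 3.07 differed by 0.32, less than the spread between arrays allows to separate (exact permutation test, two-sided, p = 0.56, 400 relabellings, smallest possible p 0.005).

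**Figure D3:**
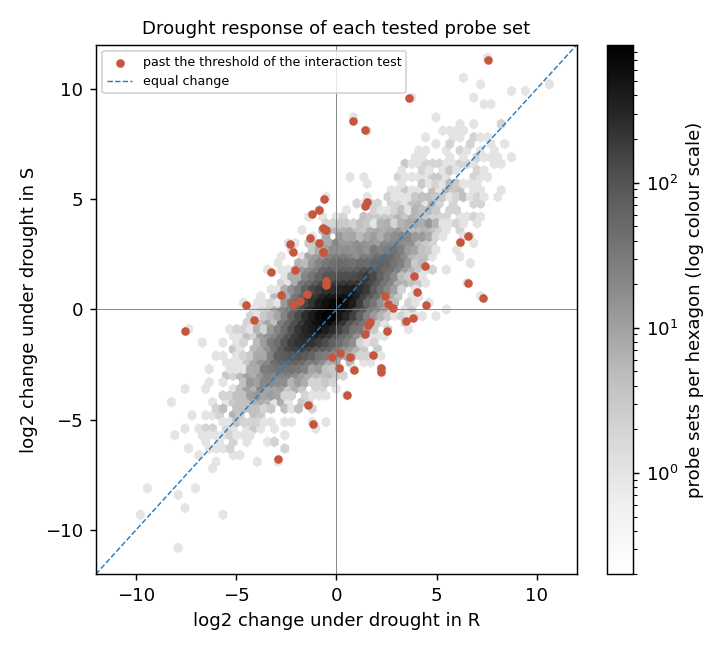
Log2 change under drought in R (x axis) and in S (y axis) for the 38398 tested probe sets, with darker hexagons holding more probe sets on a log colour scale. The dashed line marks equal change, and red points are the 57 probe sets past the threshold of the interaction test, while the bulk follows the diagonal with r = 0.74.

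Between genotypes, 2797 probe sets differed in well-watered plants, 1676 higher and 1121 lower in R. TBP1 was lower in R by a log2 difference of −1.07 (adjusted p = 0.016), with 877 ± 231 signal in R and 1824 ± 274 in S (SD, n = 3). None of the other 7 genes with a symbol passed the threshold as deposited. CAT1 differed by −0.71 (adjusted p = 0.067) and passed it with median scaling (−1, adjusted p = 0.035) and without R well-watered replicate 2 or R drought replicate 1 (adjusted p = 0.032 and 0.039). The unnamed probe sets with the highest differences were at least 136-fold and 56.3-fold higher in R (adjusted p = 1e-07 and 2.2e-08). Of the lowest 2, one had 79.7 ± 64.6 signal in R against 37682 ± 10448 in S, and the other was at least 53.6-fold lower in R (adjusted p = 2.4e-07 for both). LOC606308 was at least 4.1-fold higher in R, LOC543440 was at least 10.9-fold lower, and LOC542947 measured 3564 ± 2527 in R against 76487 ± 9214 in S (adjusted p = 0.0015, 4.1e-05 and 5.8e-05). The LOC606308 call was lost with signals under the control level set to it (1.92, adjusted p = 0.093). The split of higher to lower turned with the scaling and was 1122 to 1726 with median scaling, 1441 to 1418 with quantile normalization, 820 to 817 with hybridization control scaling and 1313 to 484 with poly-A control scaling. The count fell to 1555, 1854 and 1546 without R well-watered replicate 1, R well-watered replicate 3 and S well-watered replicate 1, and TBP1 lost its call without either of the last 2 arrays (adjusted p = 0.065 and 0.08), with hybridization control scaling, where its difference was larger at −1.34 (adjusted p = 0.12), and with poly-A control scaling (−0.88, adjusted p = 0.33). The count was 1637 with hybridization control scaling and 1797 with poly-A control scaling.

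Under drought, 2873 probe sets differed between genotypes, 1373 higher and 1500 lower in R. One unnamed probe set was at least 447-fold higher in R (adjusted p = 0.00064), and another measured 16078 ± 3543 in R and 60.4 ± 66.8 in S (adjusted p = 4.7e-07). The lowest was at least 125-fold lower in R (adjusted p = 1.7e-06). LOC606308 was at least 15.9-fold higher in R (adjusted p = 0.00028), LOC606366 had a log2 difference of 4.71 ± 0.83 (adjusted p = 0.0028), and LOC543479 and LOC100037659 differed by −6.83 ± 0.70 and −5.25 ± 0.44 (adjusted p = 2.6e-05 and 4.7e-06). LOC543479 was above the control level on 1 of the 3 R arrays, so the size of its difference is not exact. No gene with a symbol passed the threshold (limma), though GAPN, at −1.13 (adjusted p = 0.2), passed it with a larger difference without R drought replicate 3 (adjusted p = 0.025). XTH came nearest as deposited, at −2.14 ± 0.64 (adjusted p = 0.057), but most of its signals lay below the control level. With those set to that level, its difference was −0.34 (adjusted p = 0.43). In both regimes, 1164 probe sets differed in the same direction, 650 higher and 514 lower in R against 60 and 44 for independent lists, and 8 in opposite directions. The numbers for independent lists can again be too low, since the same fit gave both lists. The split was 1603 higher and 1125 lower with median scaling, 2119 and 514 with hybridization control scaling, and 785 and 967 with poly-A control scaling. With poly-A control scaling the count fell to 1752. The count fell to 1737, 1877, 1714 and 1892 without R drought replicates 1 and 2 and S drought replicates 2 and 3.

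A different drought response in the genotypes was found for 57 probe sets, 29 with a more positive change in R and 28 with a more negative one. LOC543479 measured 2.72 ± 0.635 in well-watered S and 8817 ± 7362 under drought, but 23.6 ± 25.7 and 64.4 ± 64 in R, an interaction of −7.73 ± 0.99 (adjusted p = 0.0063). The unnamed probe set with the highest interaction measured 21.9 ± 20 and 5555 ± 1608 in R, but 63.3 ± 46.2 and 83.5 ± 10.9 in S, an interaction of 6.78 ± 0.70 (adjusted p = 0.00093). LOC543338 measured 44 ± 27.2 in well-watered R and 896 ± 255 in well-watered S, and 5638 ± 2596 and 9239 ± 2600 under drought (interaction 3.25 ± 0.56, adjusted p = 0.037). LOC543440 measured 58.7 ± 34.1 and 741 ± 97.9 in R, against 1421 ± 222 and 1111 ± 696 in S (interaction 4.01 ± 0.65, adjusted p = 0.027). LOC543258 fell in both genotypes, from 234 ± 87.2 to 76.2 ± 10.2 in R and from 3202 ± 627 to 145 ± 28.5 in S (interaction 2.93 ± 0.46, adjusted p = 0.025). For each of these 5 probe sets at least 1 group lay below the control level on all 3 arrays, so the sizes of the interactions are not exact. With signals under that level set to it, a choice made after the data were seen, they were 5.22 for the unnamed probe set (adjusted p = 3.1e-05), −5.59 for LOC543479 (adjusted p = 0.0011), 2.92 for LOC543440 (0.021), 3.53 for LOC543258 (0.0015) and 1.85 for LOC543338, which was then no longer past the threshold (0.056). For LOC543258 this setting cuts off the fall in R, to 76.2 ± 10.2, more than the fall in S, to 145 ± 28.5. It can by itself raise that interaction, so the value of 3.53 is no check of it. That setting called 563 probe sets, 254 with a more positive change in R and 309 with a more negative one. With the values as deposited, no gene with a symbol and no sucrose synthase probe set passed this test. The split became 133 to 29 with median scaling, 42 to 23 with quantile normalization, 112 to 14 with hybridization control scaling and, the other way, 12 to 41 with poly-A control scaling. Leaving out 1 array gave 17 to 104 probe sets. LOC543440 and LOC543338 lost their calls without 9 and 8 of the 12 arrays (adjusted p up to 0.083 and 0.11), among them R drought replicates 1 and 2, R well-watered replicate 1, the 3 S well-watered arrays and S drought replicate 3 for both, R well-watered replicate 3 and R drought replicate 3 for LOC543440, and S drought replicate 2 for LOC543338. LOC543258 lost its call without any 1 of 6 arrays (R well-watered replicate 1, R drought replicates 1 and 2, S well-watered replicates 1 and 2 and S drought replicate 3, adjusted p up to 0.083). Over the 12 arrays left out, the interactions stayed at 3.50 to 4.48, 2.82 to 3.55 and 2.68 to 3.19 for LOC543440, LOC543338 and LOC543258. The 3 calls were also lost with poly-A control scaling, with somewhat smaller interactions of 3.72, 3 and 2.65 (adjusted p = 0.057, 0.065 and 0.13).

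Among control transcripts, ubiquitin did not pass the threshold for drought in either genotype at any of its 3 probe sets, with log2 changes of −0.28 to −0.39 in R and −0.02 to −0.32 in S as deposited, and its changes in R lay above 0 with median scaling and hybridization control scaling. With quantile normalization, its 3′ probe set passed the threshold in R (−0.52, adjusted p = 0.04), as it did without R well-watered replicate 1 (−0.53, adjusted p = 0.045). The 3′ and middle probe sets of glucose-6-phosphate dehydrogenase (G-6-PDH), of the oxidative pentose phosphate pathway, measured −0.74 ± 0.24 and −1.06 ± 0.30 in R (adjusted p = 0.026 and 0.015), and the 3′ value turned to 0.17 under hybridization control scaling. Both calls were lost with median scaling (−0.25 and −0.57, adjusted p = 0.56 and 0.21), hybridization control scaling (0.17 and −0.16, adjusted p = 0.83 and 0.85) and poly-A control scaling (−0.62 and −0.94, adjusted p = 0.38 and 0.2). The same G-6-PDH probe sets measured −0.41 and −0.42 in S (adjusted p = 0.23 and 0.35) and −0.58 and −0.74 on average (adjusted p = 0.012 for both). The average calls were lost with the same 3 scalings (adjusted p = 0.12 to 0.85). In well-watered plants the middle probe set was higher in R than in S by 1.16 (adjusted p = 0.034). That call was lost with these 3 scalings (adjusted p = 0.13 to 0.44) and without any 1 of 5 arrays (adjusted p up to 0.14). The G-6-PDH 3′ call for drought in R was lost without R well-watered replicate 1 or any of the 3 R drought arrays (−0.84 to −0.59, adjusted p up to 0.1). The middle actin probe sets measured 0.09 and 0.12 for drought in R, −0.46 and −0.08 in S, and −0.18 and 0.02 on average. None of these passed the threshold (adjusted p = 0.51 to 0.96). Nor did the actin 5′ probe set, at −0.53, −1.48 and −1.01 in the same order (adjusted p = 0.62, 0.15 and 0.14). Only the actin 3′ probe set was called. It measured −1.08 ± 0.38 in R (adjusted p = 0.043), −1.06 ± 0.38 in S (adjusted p = 0.055) and −1.07 on average (adjusted p = 0.0054). Its call in R was lost under all 4 other scalings, at −0.22 to −0.96 (adjusted p = 0.23 to 0.79), and without any 1 of 9 arrays, at −1.39 to −0.76 (up to 0.16), all but R well-watered replicate 1 and S drought replicates 1 and 2. Its average call was lost with hybridization control scaling (−0.61, adjusted p = 0.19) and poly-A control scaling (−0.82, adjusted p = 0.11). In S it passed the threshold with array weights (−1.04, adjusted p = 0.031), without the trend (0.039) and with a filter on the mean (0.042). As a measure of RNA quality, the log2 ratio of the 3′ to the 5′ probe set of ubiquitin was −1.99 ± 0.37, −2.06 ± 0.07, −1.92 ± 0.16 and −2.05 ± 0.07 in well-watered R, R under drought, well-watered S and S under drought (SD, n = 3). In the same order, the ratio was 1.82 ± 0.33, 1.68 ± 0.47, 1.83 ± 0.44 and 2.04 ± 0.27 for G-6-PDH. For sucrose synthase the group means were 3.55 to 5.03, so both of these transcripts gave more signal at the 3′ probe set.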

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

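The tests of scaling, of the array that stands apart, of calls in 1 genotype and of sibling probe sets were chosen after the results they bear on had been seen.

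The drought responses of the genotypes differed, by the interaction test, for 57 probe sets. Genotype was reassigned within each water regime, with the genotype main effect removed. Of 100 such splits, 1 (the real one) gave as many probe sets, and the highest of the others gave 23. In the other splits a real interaction adds to the spread within groups, which can lower their counts. The splits were run in the main setting alone. With 1 array left out the real count fell as low as 17, so chance is not excluded for every setting. The members with a gene are LOC543479 (−7.73), LOC543440 (4.01), LOC543338 (3.25) and LOC543258 (2.93), and 3 unnamed probe sets had interactions of 6.78, 5.38 and −6.72. Each of these 7 has at least 1 group below the control level on all 3 arrays, so these sizes are not exact, and with signals under that level set to it LOC543338 was not past the threshold (1.85, adjusted p = 0.056, limma). The one at −6.72 measured 22998 ± 14147 in S under drought and 94.4 ± 33.6 in R under drought, and the one at 5.38 measured 93.3 ± 44.7 and 16280 ± 5538 (SD, n = 3). The one at −6.72 lost its call without R well-watered replicate 3 or S drought replicate 3 (adjusted p = 0.051 and 0.07).

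For drought averaged over the genotypes, the regime was reassigned within each genotype. Of 100 such splits, 1 (the real one) gave as many as the real 15887, and the highest of the others gave 498. A chance division of the arrays was thus not seen to come near this count, though a real drought effect can lower the counts of the other splits. For the contrasts of 3 arrays against 3, the 10 possible splits are too few for a share under 0.05, and in each contrast 1 split, the real one, gave as many. The real counts and the highest of the other splits were 12824 and 0 for drought in R, 10461 and 0 for drought in S, 2797 and 6 for R minus S in well-watered plants, and 2873 and 25 under drought.

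In R, 59.3% of the drought calls were lower. The share was 36.5% with median scaling and 48.3% with quantile normalization. Both recentre the arrays and so largely set this balance themselves. The excess of lower calls thus depends on the scaling and may come from the scaling to 1 trimmed mean, but these shares do not decide it. Well-watered R replicate 3, with its high median signal, is not the whole source, because 56.5% of the calls were lower without it. The SD of this share over the R arrays left out was 1.28. That SD shows how far leaving out 1 array moves the share and is not a sampling error. A fall in transcripts per cell under drought in R cannot be told apart from scaling, since scaling to poly-A controls gave 55.2% and scaling to hybridization controls 19.6%, and the labels do not say how these controls were added.

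Of the probe sets called for drought in R alone, 84.4% had the same direction in S, each taken relative to its median change, with a median ratio of S to R of 0.39. For S alone the share was 77.2% and the median ratio of R to S 0.27, while probe sets called in neither genotype shared direction in 60.3%. A threshold applied to a response that both genotypes share may therefore account for many of these 8263 calls. A weaker response in either genotype stays open for them, since the interaction recovered 34.8% of simulated 8-fold differences when 200 probe sets changed. With signals under the control level set to it, 563 probe sets passed the interaction test, against 57 as deposited. A change cut off at that level in R or S alone can add to the 563, so that count does not decide the question.

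Differences between genotypes may arise from sequence differences under the probes, or from transcripts of other gene copies, as well as from transcript level. For genes with a call of at least 2-fold, the brightest other probe set of the gene above the control level also differed at least 2-fold in the same direction for 45 of 72 genes for drought in R and for 6 of 17 for R minus S in well-watered plants (Fisher's exact test, two-sided, p = 0.057). The numbers were 43 of 67 for drought in S and 6 of 20 for R minus S under drought (Fisher's exact test, two-sided, p = 0.0098), and the Benjamini-Hochberg values over these 2 tests were 0.057 and 0.02. Changes of at least 2-fold were also called more often for drought. These were 11072 probe sets in R and 8973 in S, against 2560 and 2621 for R minus S in well-watered plants and under drought. A partner probe set is thus likelier to agree for drought whatever the probe sequences. Sequence and level cannot be told apart here for this reason. In addition, well-watered plants alone did not reach the threshold and few genes have several probe sets. The genotype difference in transcript level itself was not tested in another way.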

How the results depend on the processing

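The replicate number did not pair the samples: residuals of same-numbered arrays correlated with r of −0.13 to 0.18 (1 of 18 pairs over 0.1), and 3 of 12 arrays were closest to their own number. With the number as a block, the counts were 12399 for drought in R, 10082 in S, 15488 for their mean, 2551 and 2652 for R minus S (well-watered and drought) and 46 for the interaction. The counts for drought in R, in S and on average stayed within 1.5 times under each alternative fixed beforehand, each array left out included. The larger count was not always that of R. Array weights gave 12084 in R and 12963 in S. Leaving out R drought replicate 1 gave 9891 in R and 10870 in S. A broader response in R was thus not shown. The interaction was 171 with a pseudocount of 64, 162 with median scaling, 18 without the trend, 87 with array weights and, added later, 126 with hybridization control scaling. With signals under the control level set to it, added later, it was 563 and the correlation 0.828. The cause was not tested, but a change cut off at that level in 1 genotype alone can add to the count of 563. Called values were also followed for genes with a symbol, control transcripts and the probe sets added after their values were seen. With signals under the control level set to it, 86 of 88 of them were kept. Hybridization control scaling also gave 6584 for drought in S and 1637 for R minus S well-watered. Poly-A control scaling, added later too, gave 8520 for drought in R, 1797 for R minus S well-watered and 1752 under drought. The cause of these moves was not tested. Leaving out each array in turn gave 9891 to 13061 for drought in R, 7211 to 10885 in S, 14245 to 16037 on average, 1546 to 3085 for R minus S well-watered, 1714 to 3046 under drought and 17 to 104 for the interaction. It gave 0.692 to 0.755 for the correlation and −0.03 to 0.63 for the difference in response score. Interaction counts more than 1.5 times apart from 57 came without R well-watered replicates 1, 2 and 3 (24, 104 and 33), R drought replicates 1 and 2 (26 and 22), S well-watered replicates 1 and 2 (27 and 18) and S drought replicate 3 (17). The correlation was 0.665 with no filter, where more dim probe sets enter, and within its jackknife SE of 0.055 otherwise, that floor excepted. With median scaling, 9680 of the 12824 probe sets called for drought in R and 9637 of the 10461 in S were called in the same direction, and 0 in the opposite one. Of 89 such called values, 75 were kept with median scaling, 82 with quantile normalization, 65 with hybridization control scaling and 62 with poly-A control scaling. With each alternative other than scaling that gave all contrasts, 77 or more were kept. Few of the losses under other scalings fell on the added probe sets, which were picked for large changes. These shares therefore overstate how well the calls of genes with a symbol and control transcripts held. With hybridization control scaling, CAT1 (0.32), an SAHH probe set (0.03), TUBA (0.22) and G-6-PDH 3′ (0.17) for drought in R changed sign, none past the threshold (adjusted p = 0.66 to 0.97). Probe sets near the control level of 129 have no reliable fold. Gene list shifts could not be run under any alternative, since no list had 3 tested genes.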

Other observations

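The count of probe sets present in 1 genotype was planned before its result was seen, as was the test of the response score in well-watered plants.

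Some probe sets behaved as present or absent by genotype in both water regimes. In all 6 arrays of R, 220 probe sets were above the control level of 129 while below it in all 6 arrays of S, and 150 showed the reverse. Of these, 41 and 38 were above 4 times that level on each array of the brighter genotype. Of 200 splits with genotype reassigned within each regime, 1 (the real one) gave as many as these 370, and the highest of the others gave 10. A gene or probe target missing from one genotype is a candidate explanation, as is a difference in expression, and the array does not separate these. By water regime, 166 probe sets were above the level in all 6 drought arrays and below it in all 6 well-watered ones, and 287 showed the reverse.

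Of locus-numbered genes not described above for their drought response, LOC606366 measured 63.8 ± 41.2 in well-watered R and 11700 ± 10470 under drought, and 76.8 ± 73.7 and 346 ± 230 in S (SD, n = 3). LOC100037659 measured 116 ± 43 and 295 ± 29.1 in R, and 581 ± 89.5 and 14030 ± 8186 in S. Neither passed the interaction test (adjusted p = 0.116 and 0.0753, limma).

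One hypothesis was that well-watered R lies nearer to the drought state than well-watered S. The drought response score of well-watered R was higher than that of S by 0.23, or 7.6% of the rise under drought in S (exact permutation test, two-sided, p = 0.3). With 3 arrays against 3, p cannot go below 0.1, so the test may miss a difference and leaves the hypothesis open.

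Of the 64 reporter probe sets, 1 was above the control level on all 12 arrays, and 0 were above both that level and each well-watered array on all drought arrays. The 3′ to 5′ log2 ratio of sucrose synthase was 4.29 ± 0.59 in well-watered R, 3.55 ± 0.38 in R under drought, 5.03 ± 1.15 in well-watered S and 4.70 ± 0.37 in S under drought (SD, n = 3). Setting signals under the control level to it lowered the drought rise of the 5′ probe set from 2.31 to 1.94 in S and from 3.1 to 2.99 in R. Its well-watered signals thus lay partly below that level, and the well-watered ratios are not exact.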
